A study of Mus musculus and Homo sapiens with 10 samples.

How the data were processed

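Gene expression was measured by RNA-seq in sorted mouse stem cells (3 Renilla and 3 Cux1-low libraries), and H3K27me3 by ChIP-seq in K562 clones (2 gHPRT and 2 gCUX1 libraries). Samples were grouped, and replicate numbers taken, from the labels. The submitters' processing notes name FastQC, STAR, DESeq2, BWA 0.7.12, SAMtools, MACS2, DiffBind and deepTools, and the builds mm10 and hg19, with no role or order given; the peak caller's settings are not given in the sources used here.

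The authors' expression table gives a normalized signal per gene and library, for 16619 rows. Each column of the deposited signal is a whole multiple of 1 step (100% of values within 0.01), so whole reads were recovered by dividing by the step. Those reads gave the depth of each library, from 14.1 to 44.4 M reads in genes, and were used for count tests added after the data were seen. 24 rows carry a gene name that had been turned into a date, 4 of which share a name. Of 713 symbols in 35 gene lists fixed before the data were examined, 656 were found as written, 1 by a synonym, 4 by an accession and 52 not at all; 14 of 18 erythroid genes, 31 of 43 homeobox genes and 29 of 58 developmental transcription factors were tested, under 80% of those lists.

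The main test was limma 3.58.1 with a mean-variance trend on log2(value + 1), Benjamini-Hochberg adjusted p under 0.05, because the table holds normalized values; fold changes are differences of mean log2 values, which weigh libraries equally and can lie above or below those of the count tools, most for genes that vary between replicates. No filter on low values was used. Replicate numbers were taken to pair the libraries, which the labels do not state. Deviations from the group mean correlated at 0.427, 0.534 and 0.627 between libraries of the same number and at -0.05 to -0.393 otherwise. Deviations sum to 0 within a group, so the negative values follow from the positive ones and add no support. Replicate 1 was the shallowest in both groups, and shared depth was not set apart from pairing. A fit with the replicate number as a block is therefore given beside the unpaired fit. A gene is said to rise, fall or change where limma with the block gave an adjusted p under 0.05. Residual degrees of freedom were 4 without and 2 with the block. Gene lists were tested with camera (preset correlation 0.01, and an estimated correlation), with Benjamini-Hochberg adjustment over 35 lists. With an estimated correlation camera tests on only the residual degrees of freedom above, so a list can fail there at any correlation. Lists were also tested with fry, a rotation test that keeps the correlation between genes and tests each list by itself. edgeR 4.0.16 and DESeq2 1.42.0 were run in R 4.3.3 on the recovered reads. Chi-square statistics of counts between libraries of a group were at least 31.3 per degree of freedom, so no library was a repeat of another.

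Named genes were chosen before the data were examined: Cux1, the 10 largest rises and falls among genes past the threshold with at least median expression, and up to 4 members of each called, repair, checkpoint or histone methylation list. Since 1 gene passed without pairing, the rule was also applied to the fit with the block. Rad51d, Flt3 and Ltf were named after their values were seen. For regions the rule asked for the 8 with the smallest FDR in each direction that lie at a gene; with no human annotation used here that condition was dropped, and regions at CUX1, EZH2 and the HOX genes were not picked out.

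The authors' deposited table of regions gives log2 mean levels for a control and a knockdown column, their log2 difference, and a p-value and an FDR per region. The peak lists, called per library by the authors, give a score, a fold enrichment (a ratio) and −log10 p and q values for each peak, per the file format. These are the authors' values and were used only to describe, filter and compare peaks. Per the file headers the table's fold is control minus knockdown; its sign was turned to knockdown minus control. Library values per region were not used here. Peaks were merged and compared with bedtools 2.31.1 at 1 base of overlap. Peak numbers and covered lengths were compared by an exact permutation test. Called regions per chromosome were compared with all regions by Fisher's exact test. Region boundaries are in hg19; no human gene annotation was used here, so tests of gene lists at regions and of H3K27me3 against expression were not run.

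Because the table and the peak lists disagreed in direction, peaks overlapping each region were counted per library, and the covered share of each region was compared with the table's difference within each replicate. The highest fold enrichment of the overlapping peaks was compared in the same way. Both sources were mapped to groups by their own labels.

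Scripts were tested on simulated data. For the stem cell comparison, counts were drawn for 13528 genes with the real pair effects. Without the block limma recovered 2.99% of 67 genes changed 1.5-fold, 49.3% of 67 changed 2-fold and 65.2% of 66 changed 3-fold. It made 0 false calls. With the block limma recovered 56.7%, 83.6% and 84.8%, or 38, 56 and 56 genes, with 22 false calls among 13298 unchanged genes. False calls were thus a larger share of the calls with the block than the adjusted p threshold allows. Genes said to rise or fall rest on that fit, so more of them may be false than the threshold implies. Pair effects were built into the simulated counts, which favours the block. A planted list was called in both fits and 0 of 34 random lists were. Random lists hold unrelated genes, while the estimated correlation was 0.824 among mature neutrophil markers, so this gives no false-call rate for the real lists. For chromosomes, 0 of 460 tests on randomly placed calls passed. Real calls clustered, with 222 adjacent pairs among regions higher in the knockdown column against a mean of 8.71 after shuffling. The 0 of 460 therefore does not carry over to them.

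Alternatives tried were other thresholds, filters, pseudocounts, scalings and count tests, leaving out each library or pair, and stricter, merged or equal-sized peak sets.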

Results

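RNA was sequenced from mouse bone marrow stem cells sorted as lineage-negative, Sca1-positive, Kit-positive and CD135-negative, after 5 days of doxycycline. There were 3 libraries carrying a hairpin against Renilla luciferase, a control target absent from the mouse genome, and 3 carrying the Cux1-low hairpin. Reads in genes ranged from 16.9 to 39.6 M in the Renilla libraries and from 14.1 to 44.4 M in the Cux1-low libraries, with replicate 1 the shallowest in both groups. In K562, a human leukemia cell line, the repressive chromatin mark H3K27me3 was mapped by ChIP-seq in clones carrying a guide against HPRT (gHPRT, control) or CUX1 (gCUX1), with 2 libraries each. The labels do not say that replicates came from separate animals or cultures, so p-values measure only the spread between these samples.

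The first comparison asks which genes differed in stem cells carrying the Cux1-low hairpin. Cux1, a homeodomain transcription factor, stood at 4870, 3963 and 5218 normalized counts in the Renilla libraries and at 2344, 1828 and 2642 in the Cux1-low libraries. Cux1 was lower in 3 of 3 pairs, by a log2 difference of -1.05 ± 0.16 (SE, n = 3 per group), with a limma adjusted p of 0.0811 without pairing and 0.0014 with the replicate pairs as a block. Myof, a membrane repair protein of the ferlin family, fell from 2049 ± 183 (SD, n = 3) to 598 ± 96.4 (SD, n = 3) normalized counts, a log2 change of -1.78, and was the 1 gene past an adjusted p of 0.05 without pairing (limma adjusted p = 0.0288). With the replicate block 3667 of 16619 genes passed, 1906 higher and 1761 lower in Cux1-low cells. Scaling to total reads in place of the authors' size factors turned that split to 1196 higher and 2264 lower. In simulated data a larger share of the calls with the block was false than the adjusted p threshold allows. Without pairing, 3281 genes had an unadjusted p under 0.05, edgeR called 1 gene and DESeq2 1338. Leaving out any 1 library left 0 limma calls, Myof included, and leaving out any 1 pair left 0 with the block, where DESeq2 with the pairs still called 1242 to 1677 genes.

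Genes of stem cell identity and of the megakaryocyte lineage fell together. Each library pools many sorted cells. Whether levels changed within cells or the mix of sorted cells differed was not tested, here or for the lists below. Of 35 tested genes of stem cell quiescence and identity, 25 fell and 2 rose with the replicate block, and the median log2 difference was -0.80. Mecom, a zinc finger factor needed for stem cell maintenance, fell from 2516 ± 567 to 882 ± 425 normalized counts (SD, n = 3), and Procr, a surface marker of stem cells, from 1653 ± 372 to 698.5 ± 156 (SD, n = 3). Hlf and Fgd5, both stem cell markers, changed by -1.44 and -1.31 on the log2 scale. The list was lower than other genes by camera (adjusted p = 6.15e-08), and the adjusted p was 0.394 with an estimated correlation. Adjusted over the list alone, 1 gene rose and 21 fell without pairing, and 4 rose and 25 fell with the block. Of 15 megakaryocyte genes all 15 were lower and 9 fell with the block. Vwf and Gp9, both made by platelets and their precursors, and the transcription factor Nfe2 fell by 1.16, 1.22 and 0.52 on the log2 scale. The megakaryocyte list had an adjusted p of 2.07e-06 by camera, and adjusted p = 0.394 with an estimated correlation.

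Of 31 homeobox genes 13 fell and 0 rose with the block, with a median log2 difference of -0.65 (camera adjusted p = 6.91e-05; adjusted p = 0.417 with an estimated correlation). Meis1, a cofactor of HOX proteins, changed by -0.87, Hoxb3 by -1.12 and Hoxa9 by -0.60. Among genes with at least median expression, the 10 largest falls with the block were those of Myof, Prkg1, Trpc6, Mecom, Hacd4, Mamdc2, Sgsm1, Mycn, Hlf and Tgm2. Prkg1, a cGMP-dependent kinase, changed by -1.77 and Tgm2, a transglutaminase, by -1.40 on the log2 scale.

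**Figure D1:**
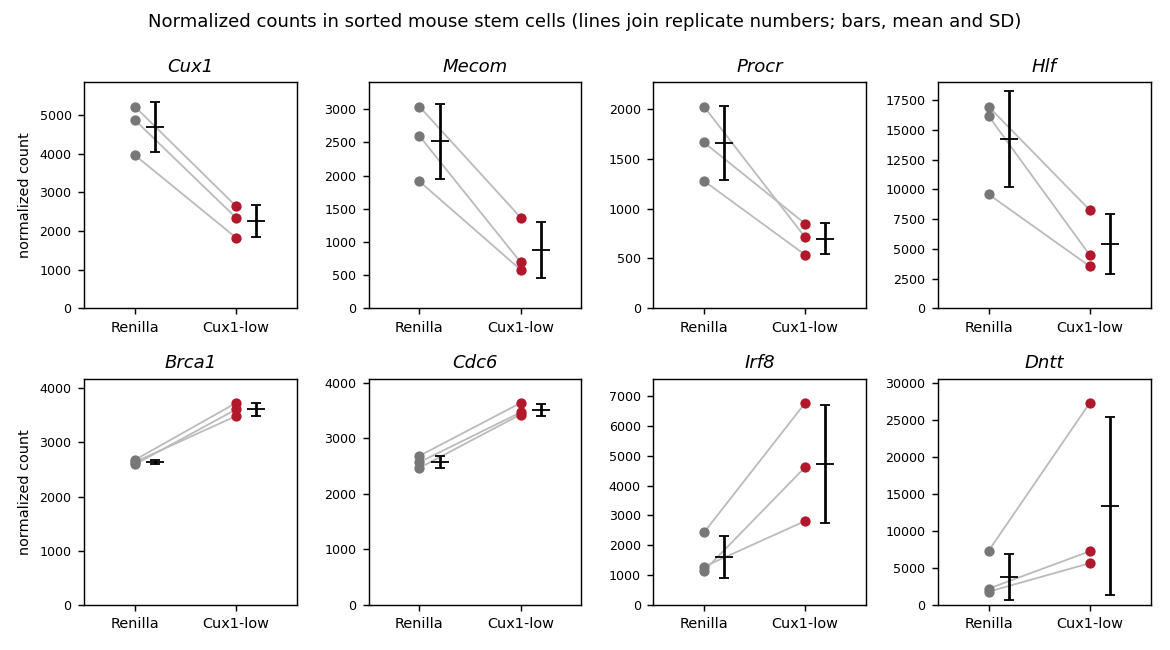
Normalized counts of 8 genes in each library, with grey lines joining libraries of the same replicate number and bars giving the mean and SD of 3 libraries. Cux1 lies between 3963 and 5218 in the Renilla libraries and between 1828 and 2642 in the Cux1-low libraries, and Brca1 between 2593 and 2676 against 3488 and 3729.

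Genes of the cell cycle rose. Of 29 DNA replication genes all 29 were higher and 26 rose with the block (median log2 difference 0.39), and of 24 mitosis genes all 24 were higher and 21 rose (median 0.52). Cdc6, which loads the replicative helicase, rose from 2575 ± 108 to 3513 ± 111 normalized counts (SD, n = 3), and Rrm2, a subunit of ribonucleotide reductase, by 0.80 on the log2 scale. Birc5 and Plk1, regulators of chromosome segregation, rose by 0.63 and 0.69. Adjusted p by camera was 2e-15 for replication and 1.43e-15 for mitosis, and adjusted p = 0.394 for both with an estimated correlation.

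The 7 lists of DNA repair and checkpoint genes had medians above 0, and 4 of them passed. Of 25 homologous recombination genes 24 were higher, and 14 rose and 1, Rad51d, fell with the block (median log2 difference 0.35). Brca1 rose from 2635 ± 41.5 to 3609 ± 120 normalized counts (SD, n = 3), with limma adjusted p = 0.0811 without and 0.00519 with the block. Exo1, Rad51ap1 and Rad54l rose by 0.51, 0.42 and 0.43 on the log2 scale. In the Fanconi anemia pathway 5 of 16 genes rose and 1 fell, with Fancd2 at 0.53 and Usp1 at 0.37. Of 18 checkpoint genes 7 rose and 1 fell, among them Clspn at 0.45 and Timeless at 0.40, both parts of the replication fork. In base excision repair 7 of 19 genes rose and 1 fell, with Fen1 at 0.43 and Neil2 at -1.71. Camera gave adjusted p = 4.14e-08 for homologous recombination, 0.00159 for the Fanconi pathway, 0.00267 for the checkpoint and 0.0414 for base excision repair. With an estimated correlation the adjusted p was 0.394 for the first 3 and 0.417 for base excision repair, whose unpaired call also ended without replicate 1 (0.0594) and without replicate 2 (0.108) but held with the block (0.027 and 0.0404). With log2 fold change as the statistic the calls ended for the Fanconi pathway and the checkpoint (adjusted p = 0.325 for both) and for base excision repair (0.476). Adjusted over the list alone without pairing, 12 homologous recombination genes rose and 1 fell. Counted so, 24 of 29 replication and 22 of 24 mitosis genes rose. Far fewer did so in other lists: 3 of 16 early myeloid, 2 of 16 lymphoid priming, 0 of 14 B cell and 0 of 27 oxidative phosphorylation genes. Of 15 megakaryocyte genes 3 fell. Replication and mitosis genes rose in the same libraries, and whether repair genes rose apart from them was not tested.

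End joining, mismatch repair and nucleotide excision repair did not differ from other genes by camera (adjusted p = 0.399, 0.144 and 0.248), with medians of 0.08, 0.07 and 0.07. Single members rose with the block, among them Polq by 0.52, Parp1 by 0.48, Lig1 by 0.40 and Rad23b by 0.23. Targets of p53 had a median of -0.02 (adjusted p = 0.399). Of 35 histone methylation enzymes 4 rose and 5 fell with the block, with a median near 0 (camera adjusted p = 0.77). Ezh2, the catalytic subunit that writes H3K27me3, rose by 0.38 and Suv39h1, which writes H3K9me3, by 0.43, while Kdm5b, an H3K4 demethylase, fell by 0.50 on the log2 scale.

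Genes of early myeloid and lymphoid differentiation were higher. Of 16 early myeloid genes 13 rose with the block and 0 fell (median log2 difference 1.14), with Irf8 at 1.55 and Csf1r, a macrophage growth factor receptor, at 1.82. Mpo, the granule peroxidase, rose from 77600 ± 57320 to 212400 ± 129500 normalized counts (SD, n = 3). Of 16 lymphoid priming genes 10 rose (median 1.08), with Dntt, the terminal transferase, at 1.76, Rag1 at 2.36, Il7r at 1.90 and Satb1 at 0.70. Camera gave adjusted p = 4.26e-05 for the myeloid and 0.000769 for the lymphoid list, and adjusted p = 0.417 and 0.394 with an estimated correlation. Flt3, which encodes the CD135 antigen used in the sort, was at 0.05.

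Some markers of B cells, neutrophils, monocytes and mast cells rose. Of 14 B cell markers 8 rose with the block, among them Pax5 at 3.45, Igll1 at 2.80, Cd79a at 2.78 and Vpreb3 at 2.77 on the log2 scale. From recovered reads edgeR gave smaller differences for Pax5, Igll1, Cd79a and Vpreb3, of 2.36, 1.95, 2.04 and 2.06. Cd79a was at 57.5, 1565 and 41.8 normalized counts in Renilla replicates 1, 2 and 3, and at 814, 6007 and 256 in the Cux1-low replicates. Of the 10 largest rises with the block among genes with at least median expression, Pou2af1, Ebf1, Igll1, Cd79a, Vpreb3, Lef1, Blnk and Vpreb1 belong to B or early lymphoid cells, beside Hspa1b and Gfra2. Of 12 mature neutrophil markers 3 rose, and the granule gene Ltf reached 8583 normalized counts in Cux1-low replicate 1 but 321 and 30.1 in replicates 2 and 3. Of 14 monocyte markers 4 rose, with Cx3cr1 at 1.78, and of 11 mast cell and basophil markers 6 rose, with Cpa3 at 0.94 and Prss34 at 1.69. Camera adjusted p was 0.0414 for B cells, 0.00566 for neutrophils, 0.0376 for monocytes and 0.00482 for mast cells. With an estimated correlation the adjusted p was 0.597, 0.529, 0.597 and 0.394. In the unpaired fit the calls ended without replicate 1 for B cells (adjusted p = 0.615), neutrophils (0.274) and monocytes (0.521), and without replicate 3 for B cells (0.0714) and mast cells (0.0862). With the block the B cell call held without each pair (0.0191, 0.00287 and 0.00234), while those of neutrophils (0.63) and monocytes (0.251) ended without replicate 1, monocytes without replicate 2 (0.109) and mast cells without replicate 3 (0.0979). T and NK cell markers (median 0.34, adjusted p = 0.219), stromal and endothelial markers (median -0.12, adjusted p = 0.745) and erythroid genes (median 0.15, adjusted p = 0.25) did not differ from other genes with all libraries, but the erythroid list was higher without replicate 2 (adjusted p = 0.00263).

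**Figure D2:**
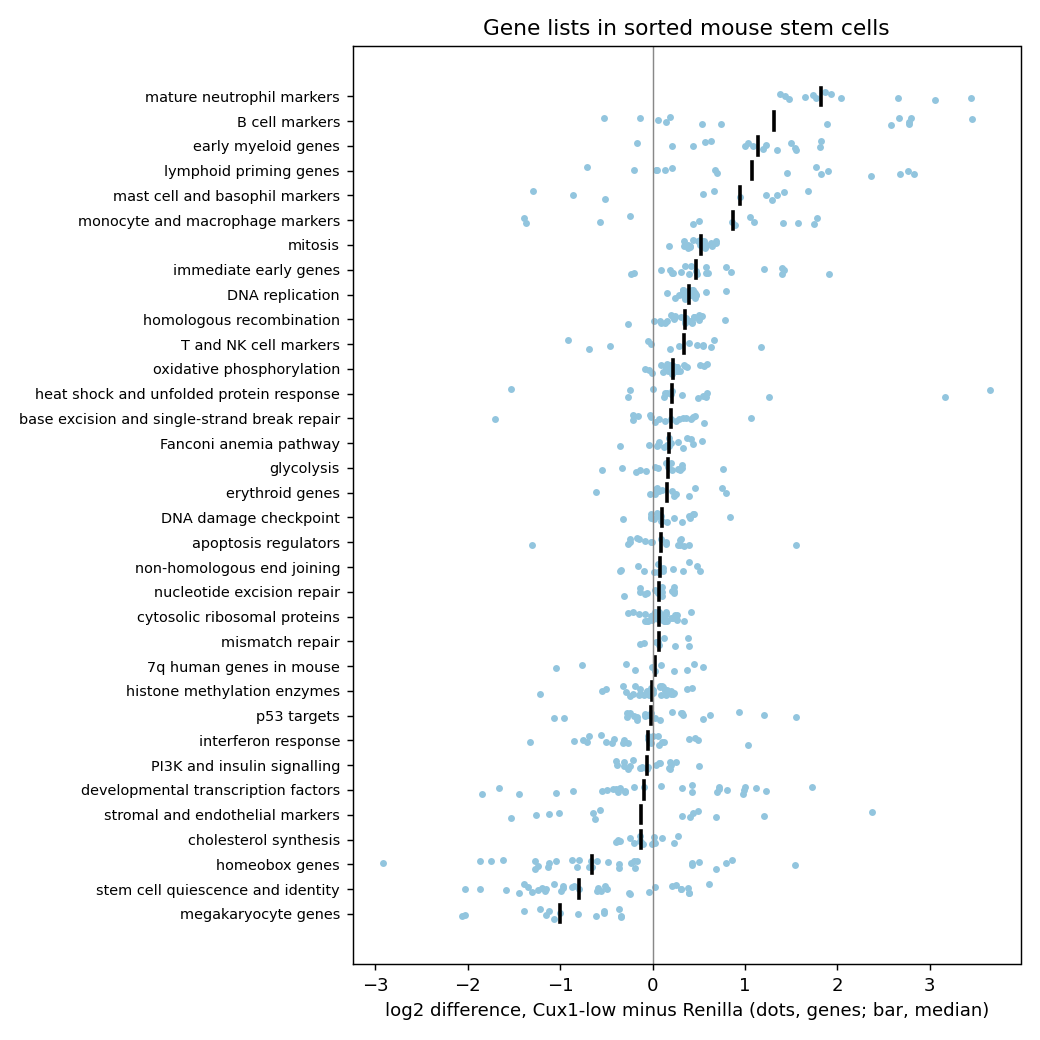
Log2 difference, Cux1-low minus Renilla, of each gene (dots) in each list except the sex-linked genes, with the list median as a black bar. The median is -0.80 for stem cell genes, 0.52 for mitosis genes and 1.82 for mature neutrophil markers.

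Several other lists were higher in Cux1-low cells. Of 27 oxidative phosphorylation genes 14 rose with the block, with Cox5a at 0.59 (camera adjusted p = 8.59e-06; adjusted p = 0.417 with an estimated correlation). Of 17 heat shock and unfolded protein response genes 7 rose and 1 fell, with the chaperone Hspa5 at 0.59, Hspa1a at 3.65 (2.92 by edgeR) and Trib3 at -1.54 (adjusted p = 0.0254; adjusted p = 0.394 with an estimated correlation). Immediate early genes (2 of 22 rose; Btg2 at 1.20) had an adjusted p of 0.00397, and adjusted p = 0.417 with an estimated correlation. Ribosomal protein genes (3 of 37 rose and 1 fell; Rps2 at 0.41) had an adjusted p of 0.0443, and adjusted p = 0.545 with an estimated correlation. The list of 6 sex-linked genes, 5 of them lower and 1 higher, passed as lower (adjusted p = 0.0414; adjusted p = 0.417 with an estimated correlation), with Xist at 32.4 in Renilla and 6.36 in Cux1-low cells on average. Both Xist means lie below the median gene mean of 577.5. The list mixes Xist and Tsix with the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty. A shared direction therefore says nothing about the sex of the animals. In the unpaired fit, leaving out replicate 2 or replicate 3 ended the calls of the heat shock list (adjusted p = 0.0642 and 0.0721), the immediate early genes (0.225 and 0.059) and the ribosomal proteins (0.114 and 0.121). The sex-linked call ended without replicate 1 (0.0965) and without replicate 2 (0.179). With the block the heat shock call held without replicate 2 (0.0433) but not replicate 3 (0.075), and the sex-linked call without replicate 1 (0.0311) but not replicate 2 (0.0551). The immediate early (0.257 and 0.0679) and ribosomal calls (0.117 and 0.063) ended with the block too. Interferon response genes passed as lower with the block (9 of 26 fell and 2 rose; adjusted p = 0.0245) but not without it (0.114), with Oasl2 at -0.71 and Bst2 at 0.49, and adjusted p = 0.523 with an estimated correlation in the fit with the block. Without the block they passed among genes of at least median expression (0.0425) and without replicate 1 (0.0107), but not without replicate 2 (0.144) or replicate 3 (0.694), and the call with the block ended without replicate 3 (0.414). PI3K and insulin signalling (adjusted p = 0.248), apoptosis regulators (0.354), glycolysis (0.392), cholesterol synthesis (0.114), developmental transcription factors (0.934) and mouse counterparts of human 7q genes (0.934) did not differ from other genes by camera, except that cholesterol synthesis was lower among genes of at least median expression (0.0425). In all 20 lists passed without pairing and 21 with the replicate block, and 0 passed in either fit with an estimated correlation. That test has only 4 or 2 residual degrees of freedom, so lists can fail it whatever their correlation. The checkpoint list failed it at an estimated correlation of -0.013, under the preset 0.01. By fry without pairing, only homologous recombination and the checkpoint had an FDR under 0.05 (0.0249 for both). With the block both passed by fry, as did replication, lymphoid priming and homeobox genes, among others (0.0427 each). Stem cell (0.0504), mitosis (0.12), megakaryocyte (0.0845), early myeloid (0.0844) and B cell lists (0.152) did not. Other splits of the 6 libraries gave up to 18 lists by camera. None of them spreads the Cux1-low libraries evenly, so they can keep part of the real difference. They do not measure how many lists pass without one. The preset correlation of 0.01 lies below estimates such as 0.746 for mitosis, so the set tests are weaker evidence than their p-values alone.

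The second comparison asks where H3K27me3 differed between gCUX1 and gHPRT cells. The peak lists held 39022 and 71026 peaks in gHPRT replicates 1 and 2, and 46659 and 65239 in gCUX1 replicates 1 and 2. Peaks covered 239 and 304 Mb in gHPRT and 156 and 270 Mb in gCUX1, a ratio of gCUX1 to gHPRT of 0.652 in replicate 1 and 0.888 in replicate 2. In replicate 2 that direction turned with stricter peaks: the ratio was 1.75 at −log10 q of at least 5 and 1.57 at fold enrichment of at least 4, against 0.0287 and 0.0904 in replicate 1. The exact two-sided permutation p was 1.0 for peak number and 0.667 for covered length, where 2 against 2 libraries cannot go below 0.333. Replicates were also called differently. The lowest −log10 q was 1.01 in both replicate 1 lists but 0.225 and 0.314 in the replicate 2 lists, and the median fold enrichment given by the authors was 2.95 and 3.03 against 1.79 and 1.78.

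Peaks of the libraries overlapped about as much within groups as between them. The Jaccard index in bases was 0.565 for the gHPRT pair and 0.502 for the gCUX1 pair, and between 0.452 and 0.591 across groups, with means of 0.534 and 0.522. Of 76235 merged regions, 18609 held a peak in all 4 libraries, 2753 in both gHPRT libraries alone and 947 in both gCUX1 libraries alone. Parting the libraries by replicate number gave 8290 regions in replicate 2 alone and 108 in replicate 1 alone, and the crossed pairs gave 704 and 1017.

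The authors' deposited table of 42932 regions pointed the other way from the peak lists. At FDR under 0.05 the authors' deposited table held 615 regions with the higher mean in the column headed knockdown and 93 with the higher mean in the column headed control. Yet all 615 of the first kind had a called peak in both gHPRT libraries, against 171 and 286 in gCUX1 replicates 1 and 2, and all 93 of the second kind had one in both gCUX1 libraries, against 2 and 11 in gHPRT. Every one of the 42932 regions had a peak in 2 or more libraries. Of them 28150 and 40606 had one in gHPRT replicates 1 and 2, and 25816 and 39021 in gCUX1 replicates 1 and 2. Across all regions the table's difference, knockdown minus control, ran against the difference in covered share of the region, gCUX1 minus gHPRT (Spearman rho -0.72 in replicate 1 and -0.457 in replicate 2, across regions, which are not independent replicates). Directions from the table are therefore given by its column headings and not as a gain or loss in CUX1-targeted cells.

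**Figure D3:**
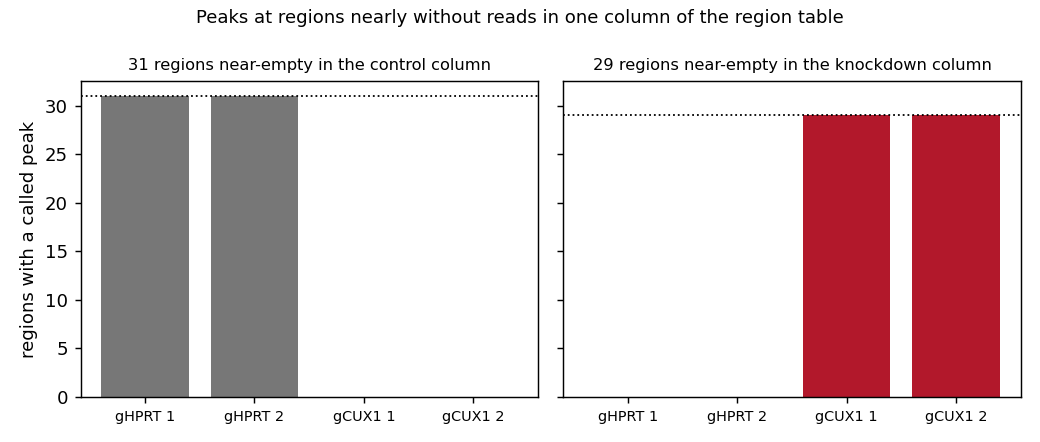
Bars give how many regions hold a called peak in each library, for regions under 1 on the log2 scale in the control column (left) or the knockdown column (right) of the authors' deposited table; dotted lines mark all such regions. The 31 regions on the left have peaks in both gHPRT libraries and none in gCUX1, and the 29 on the right the opposite.

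Among the regions higher in the column headed knockdown, the authors' deposited table gave the smallest FDR, 2.9e-18, to chromosome 2, 152861780 to 152881063 (hg19), at 7.06 in the control and 9.59 in the knockdown column on the log2 scale. A neighbouring region of the authors' deposited table, chromosome 2, 152825117 to 152851294, stood at 7.79 and 10.12. In the authors' deposited table, chromosome 1, 160670241 to 160680583, stood at 2.10 and 8.18, and chromosome 8, 61818064 to 61829600, at 5.34 and 8.96. The other 4 with the smallest FDR in the authors' deposited table lay on chromosomes 4, 10, 8 and 5, with differences of 8.10, 3.73, 3.91 and 3.01. Among regions higher in the column headed control, the authors' deposited table gave chromosome 5, 8050074 to 8063945, at 8.77 in the control and 5.03 in the knockdown column (FDR 5.44e-17). In the authors' deposited table, chromosome 7, 105829266 to 105835763, stood at 7.73 and 1.52, and chromosome 13, 81277904 to 81285080, at 8.87 and -0.22, the lowest value in that column. The other 5 in the authors' deposited table lay on chromosomes 1, 13, 6, 13 and 5. Which genes lie in these regions was not analysed here.

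Regions higher in the column headed knockdown were unevenly spread over chromosomes. Chromosome 2 held 203 of the 615 but 3129 of the 42932 tested (Fisher's exact test, adjusted p = 1.05e-77 over 23 chromosomes), and chromosome 12 held 84 (adjusted p = 1.25e-18). Chromosome 13 held 12 of the 93 regions higher in the control column (adjusted p = 4.23e-05). Many of these lay close together, 32 of the 84 at 50 to 55 Mb on chromosome 12 and 10 of the 12 at 90 to 95 Mb on chromosome 13. On chromosome 2 the regions from 149273822 to 188900052, a segment chosen after its values were seen, stood apart: 302 of 303 had a higher value in the knockdown column, with a median log2 difference of 1.69 against 0.36 on the rest of the chromosome and 0.11 on other chromosomes. In the peak lists, covered length there relative to the rest of chromosome 2 was 0.0935 and 0.161 in gHPRT and 0.0107 and 0.0225 in gCUX1. Neighbouring regions are not independent, so the chromosome p-values overstate the evidence.

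**Figure D4:**
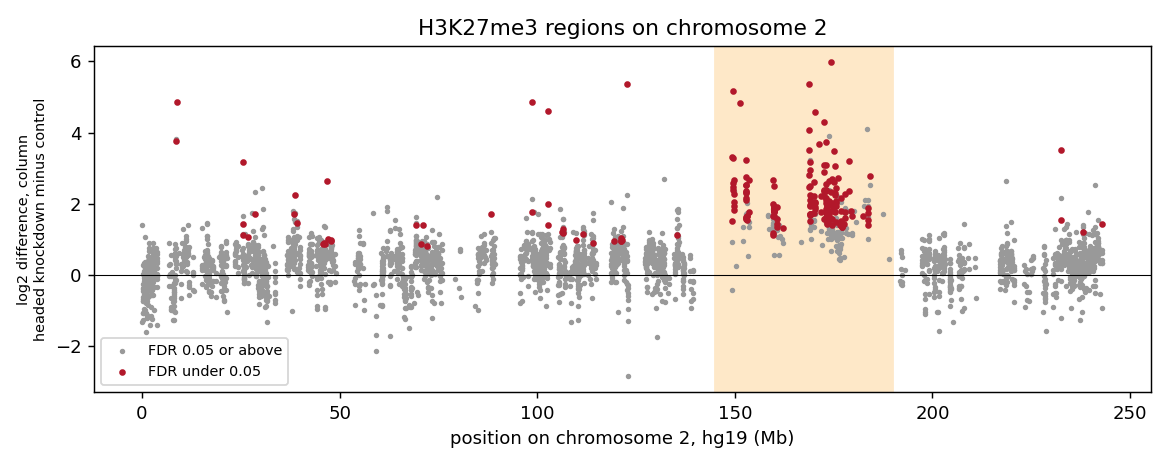
Each dot is a region of the authors' deposited table on chromosome 2 (hg19), at its start in Mb, with its log2 difference between the knockdown and control columns; red dots have FDR under 0.05 and the shaded span holds the segment from 149273822 to 188900052. Within it 302 of 303 regions lie above 0.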

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

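Chosen after seeing the data were the other tools, pseudocounts and scalings, every alternative to the fit with the replicate block, and the omissions of pairs. So were the block and the estimated correlation for lists, the alternatives for regions of the gHPRT libraries alone, and the region counts without the chromosome 2 segment or the lowest values. Without pairing, 1 gene passed at 0.05, 0 at 0.01, 405 at 0.1, 3667 with the replicate block and 1338 by DESeq2; leaving out any 1 library left 0 genes. With the replicate block 895 genes passed at 0.01, 742 with a log2 change of at least 1 and 10 by Bonferroni, and leaving out any 1 pair left 0, in fits with 1 pair fewer and so fewer degrees of freedom. DESeq2 with the pairs called 3590 genes, and 1242 to 1677 without 1 pair. The Cux1 difference passed with the replicate block (-1.05) and by DESeq2 (-1.04). Against 20 lists, 0 passed with an estimated correlation, 14 with a preset correlation of 0.05, 15 with log2 fold change as the statistic (the oxidative phosphorylation call ended at 0.104 and that of ribosomal proteins at 0.477), 15 to 16 without 1 replicate, and 12 among genes of at least median expression, of which 10 were among the 20. In that last setting 4 of the 20 had too few genes to test (monocyte, mast cell, homeobox and sex-linked), and 6 calls ended, among them B cells (0.335) and neutrophils (0.423). The block changed 1 list call, that of the interferon list. For 433 regions FDR was under 0.01, against 708 under 0.05; without the chromosome 2 segment 549 passed. The within-minus-between difference in peak overlap was 0.0117, and -0.0133 with −log10 q of at least 5. At that limit 0 regions were shared by the gCUX1 libraries alone and 24 by the gHPRT libraries alone. With 1 replicate left out, regions in 1 group alone numbered 7473 to 13823 for gCUX1 and 12430 to 20923 for gHPRT. The cause of these changes was not tested. Replicate 1 had the fewest reads in both stem cell groups, which limits low genes most. No paired analysis was possible for the region table because it holds no values per library; peak lists were compared within replicate numbers without a test. Gene lists at regions and H3K27me3 against expression were not run.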

Other observations

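All tests in this part were written down after the results they measure had been seen, including what other splits of the samples would show, although counting those splits was set before the data were examined. Without pairing, 1 of 10 splits of the 6 stem cell libraries, the real one, gave as many genes (1, against at most 0 elsewhere), and 1 of 10 gave as many lists (20, against at most 18). Among the 4 splits that part every pair, 1 gave as many genes with the block (3667, against at most 0) and 1 as many lists (21, against at most 14). So few splits cannot give a share under 0.05. No other split spreads the Cux1-low libraries evenly, so each can keep part of the real difference.

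The region table and the peak lists pointed in opposite directions in K562 cells. More peaks called in gHPRT libraries would not account for this, since 29 of 29 regions nearly empty in the knockdown column had peaks in both gCUX1 libraries. A single wrong label would turn the rank correlation with the table's difference positive in 1 replicate. In replicates 1 and 2 it was -0.72 and -0.457 for covered share, and -0.639 and -0.186 for fold enrichment. None was positive, which speaks against a single wrong label, but only weakly by fold enrichment in replicate 2. A candidate explanation is that the group labels of one source are exchanged, as 31 of 31 regions nearly empty in the control column had peaks in both gHPRT libraries and in neither gCUX1 library. Since every region has a peak in 2 or more libraries, absence from 1 group forces peaks in both libraries of the other. Peak names inside the replicate 1 lists hold the words kd and ctrl and match the groups of those lists, which speaks for the peak lists, but replicate 2 names hold no group word. This does not settle which source carries the wrong labels, so the direction of the H3K27me3 change in CUX1-targeted cells stays open.

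Regions from 149273822 to 188900052 on chromosome 2 shifted together, in limits chosen because of that shift. Shorter stretches elsewhere did so too, with 107 of 108 regions above 0 at 0 to 5 Mb on chromosome 20. At 90 to 95 Mb on chromosome 13, 0 of 15 lay above 0. Scaling of the libraries would have moved other chromosomes, whose median difference was 0.11 against 1.69 in the segment. A copy number difference between the single-cell clones is a candidate explanation: 99.7% of the regions lay above 0, which the choice of limits favours, and regions of low, middle and high level shifted by 1.62, 1.70 and 1.77. A change of the mark over the whole segment would look alike and was not tested, since no DNA copy number was used here and each group holds 2 libraries. Of the 615 regions higher in the knockdown column, 159 lie in this segment.

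The mean level of 8 early B-lineage genes was higher in Cux1-low cells in each pair, and highest in replicate 2 within both groups. These 8 genes and 6 genes of mature B cells were set apart after their values were seen, and Cd22, in neither set, rose by 1.88, so the tests that use them exclude and favour nothing. Mature B cells carried through the sort stay open (median of the 6 mature genes 0.10), and so does a larger share of early B-lineage cells (SD of the 8 genes' log2 ratios to each other 0.347). A lower share of the main cell type stays open too, since erythroid genes, with a median of 0.153, are abundant in the Renilla libraries and were higher as a list without replicate 2. Whether B-lineage cells passed the sort or arose from stem cells was not tested.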
